A study of Mus musculus with 19 samples.

How the data were processed

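The samples were whole livers of adult mice in 4 groups that crossed diet with genotype. Per the labels, control mice (C) and mice with a hepatocyte-specific knockout of PPARγ (KO) received a low fat diet (LF) or a diet high in fat, cholesterol and fructose (HF), and the knockout was induced before the 24 weeks on the HF diet. There were 4 LF-C, 4 LF-KO, 5 HF-C and 6 HF-KO libraries, 1 per mouse. Per the labels' protocols, RNA was extracted with Trizol, samples with an RNA integrity number over 7 were kept, libraries without strand information were made with a NEBNext Ultra kit at insert sizes of 250 to 300 bp, and read pairs of 150 nt came from an Illumina HiSeq instrument. Per the labels' protocols, reads were mapped to the mouse genome with STAR 2.5. The submitters' processing notes also name HTSeq 0.6.1 and DESeq2. The genome build and the gene annotation are not given in the sources used here, so gene positions are those that the deposited tables carry.

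The authors made 4 tables, 1 for each pair of groups compared. Per the file headers, each table holds read counts per gene and library, which were whole numbers. The deposited FPKM values are fragment counts relative to the listed gene length and the library total, and recomputing them from the counts, gene lengths and totals gave a largest relative deviation of 2.36e-12. The deposited log2 fold changes come from the authors' comparison of the same pairs of groups. The deposited p-values and adjusted p-values come from that comparison too, and they were used here only to count the authors' calls. Each table lists the genes with at least 1 read in its libraries, 22580 for HF-C vs LF-C, 23032 for HF-KO vs LF-KO, 23445 for HF-KO vs HF-C and 21811 for LF-KO vs LF-C. The 4 tables were joined by gene identifier into 24192 genes and 19 libraries. All 38 library columns compared between tables were identical to within 1e-09, and 0 columns lacked a sample. Of the identifiers, 23922 were present in GENCODE release M21, 16605 of them at the same start and end, and 23897 overlapped their GENCODE position.

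Counted fragments per library ranged from 11437875 in LF-C-1 to 20711869 in LF-C-2. Counts are of sequenced fragments, not of molecules, so counting error is a lower limit of the error. The spread between replicates exceeded it: over the genes with at least 20 reads in a pair of replicates of a group, the mean chi-square per gene was 7.13 or more in every pair, where counting error alone gives about 1.

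Counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM factors, the filterByExpr filter on low counts and the quasi-likelihood test. Each pair of groups was fitted on its own libraries. The difference of the KO effect between diets, (HF-KO minus HF-C) minus (LF-KO minus LF-C), was fitted on all 19 libraries. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Levels are printed as CPM, read counts relative to library size scaled with TMM factors over all 19 libraries, as mean ± SD. Fold changes are log2 values ± SE. The SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Pparg was also tested within each diet by an exact permutation test, two-sided, of log2(CPM + 1).

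The lists of genes, 28 in number with 414 members, were written from textbook knowledge of liver before the data were examined, as were the main tests, the groups and the rule for named genes. Besides the 5 alternatives given as later additions, tests chosen after the result was seen were the 3 explanations of the Pparg level, the comparison of macrophage and matrix markers with endothelial markers, and the fits of other tools without LF-KO-3 or LF-KO-4. All 414 members were found, 2 of them under an older symbol. Each list was tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. A list needed at least 5 tested members. Camera was repeated with the correlation estimated from the data. Members past an adjusted p of 0.05 were counted over all genes tested and adjusted over the list alone. In the lipid droplet list 2 members are also in the adipocyte list, and in the xenobiotic list 1 member is also in the sex-biased list.

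The named genes of a pairwise comparison are Pparg, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in at least 1 group, no overlap between the groups and a regular symbol, and up to 4 members of each list with the smallest p. For the largest rises and falls, every library thus lies beyond the other group's mean by construction. For other called genes and lists, such counts come from the libraries that gave the call, so they are no separate support. For the difference of the KO effect they are Pparg and the 10 genes with the smallest adjusted p at the same level. Families of near-identical genes (Mup, Cyp2c, Cyp3a, Cyp4a, Serpina1, Hba and Hbb, Orm, Saa, Ly6) share reads, and libraries without strand information cannot separate overlapping genes, so counts of such genes are uncertain.

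Alternatives to the scaling were median-of-ratios size factors and library size alone. Alternatives to the filter were none beyond 1 read and a mean of at least 1 CPM. Alternatives to the test were DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) of the deposited FPKM, all 19 libraries in 1 fit, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and the replicate number as a block. Each library was left out in turn. Alternatives chosen after seeing the data were fits without LF-C-1 and LF-C-2, without HF-KO-2 and HF-KO-6, or without LF-C-2 and HF-KO-2, an offset for gene length from a lowess curve per library, and limma-voom with sample quality weights. Comparisons that share libraries were compared with simulated groups without change and with the shared libraries split.

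The edgeR test was tested on simulated data with 200 changed genes per comparison. The changed genes were drawn from those with a mean of at least 5 CPM, and counts were drawn independently for each gene. Recovery at lower levels was not simulated. It recovered 23% of changes of 2-fold and 91% of 4-fold at the size of HF-C vs LF-C, 66% and 100% for HF-KO vs LF-KO, 7% and 84% for LF-KO vs LF-C, 86% and 100% for HF-KO vs HF-C, and 24% and 87% for the difference of the KO effect. Unchanged genes called were 5 of 13648 genes, 5 of 13474, 2 of 12861, 9 of 13760 and 4 of 14173.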

Results

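Gene expression was measured by RNA sequencing in whole livers of 19 mice, 1 library per mouse. The design crossed a diet with a genotype: control mice on the low fat diet (LF-C, n = 4), mice labelled as hepatocyte-specific PPARγ knockouts on the low fat diet (LF-KO, n = 4), control mice on the diet rich in fat, cholesterol and fructose (HF-C, n = 5) and KO-labelled mice on that diet (HF-KO, n = 6). PPARγ is a nuclear receptor that switches on genes of fat storage. The series design states that the HF diet was used to induce steatohepatitis, a fatty liver disease with inflammation. Counted fragments came to 11437875, 20711869, 15039154 and 15761137 in LF-C-1 to LF-C-4, and to 15948129, 17014218, 15308986 and 14447112 in LF-KO-1 to LF-KO-4. They came to 15830574, 15259151, 17120356, 16580242 and 16854323 in HF-C-1 to HF-C-5. In HF-KO-1 to HF-KO-6 they came to 16051200, 12501638, 12098671, 15317982, 14816255 and 18696031. Levels are TMM-scaled CPM (read counts relative to library size) as mean ± SD, and fold changes are log2 values ± SE. The adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood test. The number of mice in each group is as above.

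Pparg, the targeted gene (ENSMUSG00000000440, chromosome 6, 115361221 to 115490401), had more counts, not fewer, in the KO-labelled livers on the HF diet. Its level was 11.2 ± 5.74 CPM in LF-C, 25.3 ± 15.4 in LF-KO, 25.4 ± 4.32 in HF-C and 68.7 ± 25.6 in HF-KO. By library it was 18.7, 7.65, 5.94 and 12.7 CPM in LF-C-1 to LF-C-4, 35.5, 41.4, 12.6 and 11.6 in LF-KO-1 to LF-KO-4, 27.6, 25.6, 20.7, 31.3 and 21.8 in HF-C-1 to HF-C-5, and 60.3, 108, 50.8, 46.9, 52.3 and 94.0 in HF-KO-1 to HF-KO-6. All 6 HF-KO libraries lay above all 5 HF-C libraries, with a difference of 1.34 in log2(CPM + 1) and an exact permutation p of 0.00216, two-sided, the smallest that the 462 splits of these libraries allow. On the LF diet the difference was 1.01 with an exact permutation p of 0.171, two-sided, where the 70 splits allow no p under 0.0286. In the edgeR fits the log2 fold change was 1.47 ± 0.23 for HF-KO over HF-C (adjusted p = 0.00276), 1.15 ± 0.49 for LF-KO over LF-C (adjusted p = 0.704), 1.16 ± 0.31 for HF-C over LF-C (adjusted p = 0.0278, 5 of 5 libraries above the LF-C mean) and 1.44 ± 0.39 for HF-KO over LF-KO (adjusted p = 0.0546). This last value passed in DESeq2 (adjusted p = 0.00448), limma-voom (0.0408) and a fit of all 19 libraries (0.0335), and in edgeR without LF-KO-2 (log2 1.79) or HF-KO-2 (1.27). The HF-C over LF-C call was lost without HF-C-1 (adjusted p = 0.0623), HF-C-2 (0.0567), HF-C-4 (0.0653) or HF-C-5 (0.0516). The labels do not say which exons were removed, and a count per gene does not separate exons, so the genotype is written as labelled throughout and every direction between genotypes rests on the labels.

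**Figure D1:**
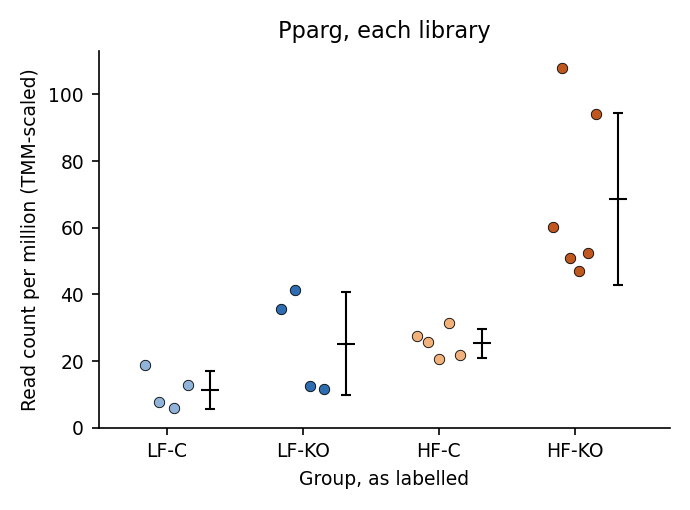
Pparg level in each liver, in TMM-scaled CPM (vertical axis), by group (horizontal axis), with a point per library and each group's mean as a dash with its SD as an error bar. The 6 HF-KO libraries, at 46.9 to 108 CPM, lie above the 5 HF-C libraries, at 20.7 to 31.3 CPM, and the LF-KO libraries span 11.6 to 41.4 CPM.

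The first comparison, HF-C vs LF-C, asks how the HF diet alters liver gene expression in control mice. On the HF diet, genes of lipid storage, collagen, recruited macrophages and cell division were higher, and genes of hepatocyte metabolism were lower. Cidec, which coats lipid droplets and favours their fusion (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), rose from 10.2 ± 3.79 CPM in LF-C to 182 ± 37.1 in HF-C, a log2 fold change of 4.13 ± 0.30. Col3a1, a fibrillar collagen chain (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706), rose from 27.6 ± 5.70 to 232 ± 68.3 CPM (log2 3.05 ± 0.25). Hsd3b5, a liver enzyme of steroid metabolism that is higher in males (ENSMUSG00000038092, chromosome 3, 98618636 to 98630309), fell from 141 ± 65.7 to 0.245 ± 0.187 CPM (log2 -9.14 ± 0.51). In edgeR's quasi-likelihood test the adjusted p-values were 6.98e-05 for Cidec, 0.000141 for Col3a1 and 3.67e-05 for Hsd3b5, with 5 of 5 HF-C libraries beyond the LF-C mean for each. For Hsd3b5, a largest fall, the rule for naming fixed that count. Of 13825 genes tested, 1469 were higher and 988 lower, 17.8% in all, and 4738 had an unadjusted p under 0.05 where 691 are expected by chance.

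Genes of fat handling and tissue remodelling rose in HF-C. Cidea, a relative of Cidec, rose by 6.23 ± 0.81 on the log2 scale to 34.4 ± 12.1 CPM, although its position overlaps B430212C06Rik. Its LF-C level was near 0, at 0 to 0.201 CPM apart from 1.5 in LF-C-2. The size of this rise is thus uncertain, and the authors' deposited log2 fold change was 2.96. Aqp7, a glycerol channel, rose by 6.08 ± 0.46 to 5.71 ± 1.34 CPM, and Cd36, a fatty acid carrier, by 1.67 ± 0.21 to 294 ± 37.0 CPM. The lipid droplet and lipid uptake list had 9 of 15 tested members higher and 1 lower (11 and 1 adjusted over the list alone), with a median log2 fold change of 1.30 and a camera adjusted p of 3.19e-05, or adjusted p = 0.111 with an estimated correlation. In the extracellular matrix and fibrosis list 23 of 25 members rose and 0 fell (23 and 0 adjusted over the list alone), among them Col1a1 (log2 3.10 ± 0.30) and Col6a3 (2.25 ± 0.29). Its median was 1.85, with a camera adjusted p of 6.68e-14, or adjusted p = 0.111 with an estimated correlation. Mmp13, a collagenase, rose by 4.91 ± 0.68 to 7.54 ± 4.78 CPM. The hepatic stellate cell markers, from the cells that deposit collagen, gave 2 higher and 1 lower of 13 (3 and 2 adjusted over the list alone), with Pdgfrb up by 1.48 ± 0.22, a median of 0.15, a mean of -0.16 that differs from it in sign, and a camera adjusted p of 0.651.

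Genes of recruited macrophages, chemokines and cell division also rose. Among recruited and lipid-associated macrophage markers 11 of 14 rose and 0 fell (13 and 0 adjusted over the list alone), including Ccr2, a chemokine receptor of monocytes, from 1.55 ± 0.268 to 19.2 ± 5.05 CPM (log2 3.60 ± 0.27) and Itgax (3.06 ± 0.31). That list had a median of 2.29 and a camera adjusted p of 3.98e-10, or adjusted p = 0.111 with an estimated correlation. Chemokines and cytokines gave 10 higher and 0 lower of 17 (10 and 1 adjusted over the list alone), with Ccl2 at 3.55 ± 0.34 and Il1rn at 2.33 ± 0.22. Its median was 1.80, with a camera adjusted p of 5.33e-07, or adjusted p = 0.111 with an estimated correlation. Cell cycle genes gave 13 higher and 0 lower of 16 (15 and 0 adjusted over the list alone), with Ccnb1, a mitotic cyclin, at 3.22 ± 0.36. Its median was 2.03, with a camera adjusted p of 7.76e-09, or adjusted p = 0.111 with an estimated correlation. Interferon response genes gave 7 higher and 0 lower of 14 (9 and 0 adjusted over the list alone), with Ifit2 at 2.18 ± 0.22. Its median was 1.05, with a camera adjusted p of 7.28e-05, or adjusted p = 0.333 with an estimated correlation. Targets of NRF2, which responds to oxidative stress, gave 6 higher and 0 lower of 12 (6 and 0 adjusted over the list alone), with Hmox1 at 1.09 ± 0.20. Its median was 0.69, with a camera adjusted p of 0.0013, or adjusted p = 0.111 with an estimated correlation. The cholangiocyte list, markers of bile duct cells, gave 5 of 10 higher and 0 lower (5 and 0 adjusted over the list alone), led by Spp1 (3.19 ± 0.37). Its median was 0.65, with a camera adjusted p of 0.0063, or adjusted p = 0.39 with an estimated correlation. That median was 1.80 without LF-C-2, and the list's adjusted p was 0.0574 without LF-C-4.

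Genes that mark hepatocyte function were lower in HF-C. The hepatocyte list had 0 higher and 9 lower of 14 (0 and 12 adjusted over the list alone), including Alb, the serum albumin, from 75600 ± 27500 to 32300 ± 4210 CPM (log2 -1.26 ± 0.27) and Ass1 of the urea cycle (-1.38 ± 0.22). Its median was -1.06, with a camera adjusted p of 7.67e-07. Of the lists called here, this call alone held with an estimated correlation (adjusted p = 0.041 with an estimated correlation). Methionine and one-carbon metabolism gave 0 higher and 13 lower of 20 (1 and 14 adjusted over the list alone), with Ahcy at -1.36 ± 0.17. Its median was -0.81, with a camera adjusted p of 4.43e-06, or adjusted p = 0.0936 with an estimated correlation. Bile acid synthesis and transport gave 0 and 6 of 16 (0 and 8 adjusted over the list alone), with Slc10a1, which takes up bile acids from blood, down from 805 ± 90.7 to 215 ± 29.7 CPM (log2 -1.93 ± 0.16) and Slco1a1, another uptake carrier, from 396 ± 107 to 19.8 ± 7.79 CPM (-4.34 ± 0.32). Its median was -0.60 with a camera adjusted p of 4.85e-05, or adjusted p = 0.146 with an estimated correlation. Cholesterol synthesis and SREBP2 targets gave 0 higher and 7 lower of 24 (0 and 7 adjusted over the list alone), with Pmvk at -1.50 ± 0.32. Its median was -0.70, with a camera adjusted p of 0.000405, or adjusted p = 0.39 with an estimated correlation. Xenobiotic metabolism gave 1 higher and 6 lower of 14 (1 and 8 adjusted over the list alone), with Cyp1a2 at -1.80 ± 0.21 and the members of shared families Cyp2c29 at -1.79 ± 0.23 and Cyp3a11 at 2.16 ± 0.29. Its median was -0.72 (-0.47 without LF-C-4), with a camera adjusted p of 0.00285, or adjusted p = 0.339 with an estimated correlation. Glucose and fructose metabolism gave 0 higher and 7 lower of 15 (0 and 8 adjusted over the list alone), with Khk, which starts fructose breakdown, at -1.64 ± 0.35. Its median was -0.58, with a camera adjusted p of 0.00285, or adjusted p = 0.109 with an estimated correlation.

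The blood and endothelial lists were called lower in HF-C by camera at the preset correlation only, while LF-C-2 stood apart from its group. Erythroid and blood markers gave 0 higher and 2 lower of 5 (0 and 5 adjusted over the list alone). Its median was -1.75, with a camera adjusted p of 0.009, or adjusted p = 0.39 with an estimated correlation. Their median was -0.48 without LF-C-2, and Hba-a1, a globin gene of a shared family, was at 202 ± 257 CPM in LF-C and 51.5 ± 10.5 in HF-C. Sinusoidal endothelial markers gave 0 and 2 of 12 (0 and 2 adjusted over the list alone). Its median was -0.41, with a camera adjusted p of 0.0382, or adjusted p = 0.581 with an estimated correlation. That call was lost without LF-C-1, LF-C-3, HF-C-2, HF-C-3 or HF-C-4 and with all 19 libraries in 1 fit, at adjusted p-values up to 0.154, and with library size alone as the scaling the median was 0.03. All list calls of this comparison moved in 5 of 5 HF-C libraries except the endothelial list, with 4 of 5. LF-C-2 had a TMM factor of 0.611, a rank correlation of -0.475 between its deviation from its group and gene length and 25.46% of its counts in 10 genes. Mitochondrial genes held 1.638% of its counts, against 4.019% in LF-C-1, 5.277% in LF-C-3 and 5.782% in LF-C-4. The correlation with gene length was also negative in LF-C-1, at -0.386, and was 0.435 in LF-C-3 and 0.428 in LF-C-4.

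The remaining lists were not called in HF-C vs LF-C. Acute phase genes gave 5 higher and 1 lower of 14 (6 and 2 adjusted over the list alone; median 0.29, camera adjusted p = 0.0697), with Lcn2, which binds bacterial iron carriers, up by 3.49 ± 0.37. Fatty acid oxidation and PPARα targets gave 5 and 2 of 24 (5 and 3 adjusted over the list alone; median 0.09, camera adjusted p = 0.651), with Pdk4 up by 2.39 ± 0.47. Kupffer cell markers, of the resident liver macrophages, gave 1 and 2 of 9 (median -0.21, camera adjusted p = 0.271), with Cd163 down from 24.0 ± 12.1 to 2.11 ± 1.40 CPM. De novo lipogenesis gave 0 and 3 of 17 (median -0.10, camera adjusted p = 0.0769), T and NK cell markers 2 and 0 of 13 (median 0.57, 0.16), B and plasma cell markers 1 and 0 of 8 (median -0.48, 0.649), and adipocyte markers 1 and 2 of 5 (median 0.74, 0.641). The circadian clock list gave 0 and 1 of 16 (median -0.40, camera adjusted p = 0.0727), the unfolded protein response 1 and 1 of 15 (median -0.20, 0.511) and sex-biased liver genes 0 and 2 of 11 (median 0.04, mean -0.15, 0.511). Neutrophil markers had 4 tested members, too few for camera, of which Csf3r rose by 1.17 ± 0.29.

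Among called genes of HF-C vs LF-C, 2455 of 2457 had every HF-C library beyond the LF-C mean. The same libraries gave the calls, so this count is no separate support. The count of lower genes was 575 without LF-C-1, 1629 without LF-C-3, 1572 without LF-C-4, 450 without HF-C-1, 505 without HF-C-2, 635 without HF-C-3, 492 without HF-C-4 and 450 without HF-C-5. Scaling by library size alone shifted the median log2 fold change of all genes by 0.40 and gave 2729 higher and 327 lower genes (89.3% higher, against 59.8%), and median-of-ratios factors gave 1329 and 1219 (52.2% higher).

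**Figure D2:**
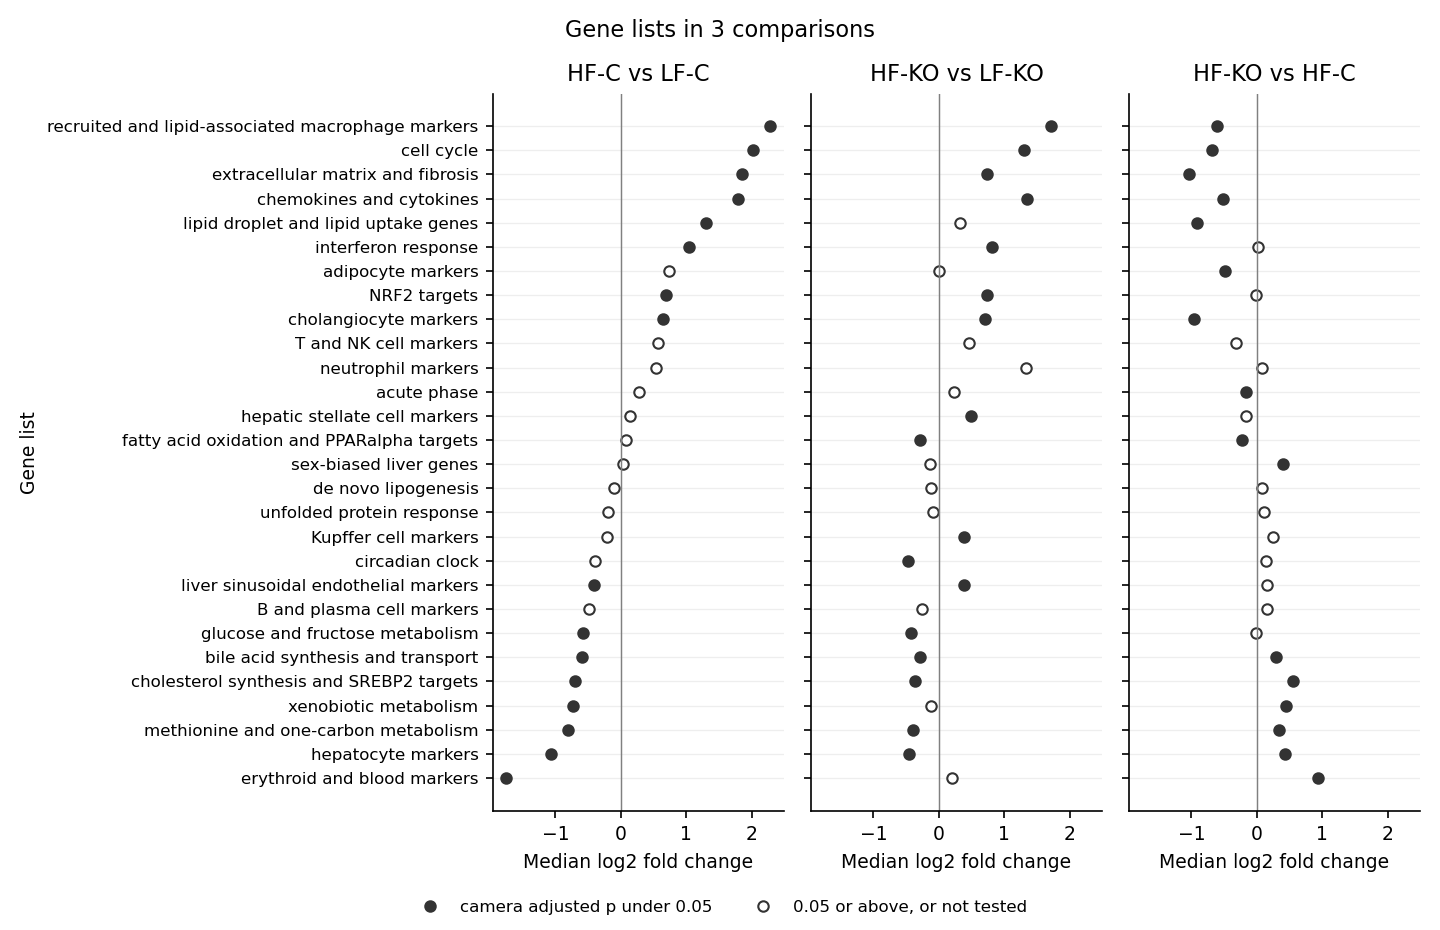
Median log2 fold change (horizontal axis) of each of the 28 gene lists (vertical axis) in HF-C vs LF-C, HF-KO vs LF-KO and HF-KO vs HF-C, with filled symbols where the camera adjusted p was under 0.05. The matrix list sits at 1.85, 0.73 and -1.04 in the 3 comparisons, and the macrophage list at 2.29, 1.71 and -0.62.

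The same diet contrast within the KO-labelled mice, HF-KO vs LF-KO, asks what the HF diet alters where PPARγ is labelled as absent from hepatocytes. Genes of macrophages, chemokines and cell division were higher and some genes of glucose and fructose metabolism were lower on the HF diet. Mmp13 (ENSMUSG00000050578, chromosome 9, 7272514 to 7283333) rose from 0.528 ± 0.281 CPM in LF-KO to 5.53 ± 2.42 in HF-KO, a log2 fold change of 3.37 ± 0.43. Pck1, which drives glucose synthesis (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), fell from 1960 ± 645 to 563 ± 152 CPM (log2 -1.80 ± 0.24). Cidec was at 8.05 ± 3.14 CPM in LF-KO and 12.4 ± 4.68 in HF-KO, which did not pass the test (log2 0.64 ± 0.31). In edgeR's quasi-likelihood test the adjusted p-values were 0.012 for Mmp13 and 0.012 for Pck1, with 6 of 6 HF-KO libraries beyond the LF-KO mean for both, and 0.277 for Cidec. Mmp13 and Pck1 were named by a rule that required no overlap between the groups, so their library counts add no support. In edgeR 0 genes were called without LF-KO-3, and Pck1 lost its call without LF-KO-4 (adjusted p = 0.0574). Of 13624 genes tested, 493 were higher and 144 lower (4.68%), and 2689 had an unadjusted p under 0.05 where 681 are expected by chance.

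Macrophage, cytokine and cell cycle lists rose in HF-KO. Recruited macrophage markers gave 11 higher and 0 lower of 14 (12 and 0 adjusted over the list alone), with Ccr2 at 1.94 ± 0.34 and Itgam at 1.80 ± 0.32. Gpnmb and Trem2, markers of lipid-laden macrophages, rose by 2.84 ± 0.70 and 2.26 ± 0.54, or 4.44 and 3.59 without LF-KO-2. The Gpnmb call was lost without LF-KO-1 (adjusted p = 0.098), LF-KO-3 (0.0983), LF-KO-4 (0.133), HF-KO-1 (0.0673), HF-KO-3 (0.0543), HF-KO-4 (0.0634), HF-KO-5 (0.0632) or HF-KO-6 (0.0913). The Trem2 call was lost without LF-KO-1 (0.0882), LF-KO-3 (0.12), LF-KO-4 (0.121), HF-KO-1 (0.0572), HF-KO-3 (0.0526), HF-KO-4 (0.0564) or HF-KO-6 (0.0832). The macrophage list's median was 1.71, with a camera adjusted p of 1.12e-12, or adjusted p = 0.0729 with an estimated correlation. Chemokines and cytokines gave 8 and 0 of 17 (13 and 0 adjusted over the list alone), with Ccl2 at 2.16 ± 0.42. Its median was 1.35, with a camera adjusted p of 1.12e-12, or adjusted p = 0.0661 with an estimated correlation. Cell cycle genes gave 7 and 0 of 15 (12 and 0 adjusted over the list alone), with Top2a at 1.87 ± 0.28 and Mki67 at 1.54 ± 0.29. Its median was 1.31, with a camera adjusted p of 2.22e-11, the list call that held here with an estimated correlation (adjusted p = 0.033 with an estimated correlation). Interferon response genes gave 6 and 0 of 14 (11 and 0 adjusted over the list alone), with Oasl2 at 0.98 ± 0.17. Its median was 0.81, with a camera adjusted p of 5.18e-08, or adjusted p = 0.104 with an estimated correlation. The matrix list gave 2 and 0 of 25 (11 and 0 adjusted over the list alone). Its median was 0.73, with a camera adjusted p of 1.18e-06, or adjusted p = 0.287 with an estimated correlation, and Col3a1 was at 30.8 ± 16.5 CPM in LF-KO and 82.7 ± 38.0 in HF-KO without passing the test (adjusted p = 0.0636). The gene calls of these lists were lost without LF-KO-3, and those of the genes named here also without LF-KO-4.

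Further lists rose in HF-KO. NRF2 targets gave 2 and 0 of 12 (2 and 0 adjusted over the list alone). Its median was 0.73, with a camera adjusted p of 7.32e-05, or adjusted p = 0.175 with an estimated correlation. Cholangiocyte markers gave 2 and 0 of 10 (2 and 0 adjusted over the list alone). Its median was 0.70, with a camera adjusted p of 0.000226, or adjusted p = 0.106 with an estimated correlation. Stellate cell markers gave 3 and 0 of 13 (7 and 0 adjusted over the list alone). Its median was 0.50, with a camera adjusted p of 0.00248, or adjusted p = 0.165 with an estimated correlation. Endothelial markers gave 1 and 0 of 12 (3 and 0 adjusted over the list alone). Its median was 0.38 (0.58 without LF-KO-1), with a camera adjusted p of 0.00231, or adjusted p = 0.291 with an estimated correlation. Kupffer cell markers gave 1 and 0 of 9 (3 and 0 adjusted over the list alone), with Cd5l at 1.52 ± 0.26. Its median was 0.39 (0.26 without LF-KO-3, 0.23 without HF-KO-2), with a camera adjusted p of 0.0116, or adjusted p = 0.291 with an estimated correlation. The Cd5l call was lost without LF-KO-3 or LF-KO-4. The matrix, stellate and Kupffer lists moved this way in 5 of 6 HF-KO libraries, and the other called lists of this comparison in 6 of 6.

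Metabolic lists fell in HF-KO. Glucose and fructose metabolism gave 0 higher and 3 lower of 15 (0 and 7 adjusted over the list alone), with Gys2, the liver glycogen synthase, at -0.95 ± 0.14. Its median was -0.43, with a camera adjusted p of 8.57e-07, or adjusted p = 0.0661 with an estimated correlation. The hepatocyte list gave 0 and 4 of 14 (0 and 7 adjusted over the list alone), with Alb at -0.68 ± 0.14 (adjusted p = 0.0581 without HF-KO-6). Its median was -0.46, with a camera adjusted p of 5.93e-07, or adjusted p = 0.0988 with an estimated correlation. Cholesterol synthesis gave 0 and 5 of 24 (0 and 7 adjusted over the list alone; median -0.36, camera adjusted p = 1.31e-05, or adjusted p = 0.165 with an estimated correlation). Methionine metabolism gave 0 and 3 of 20 (0 and 3 adjusted over the list alone), with Mat1a, which makes S-adenosylmethionine, at -0.78 ± 0.15. Its median was -0.40, with a camera adjusted p of 3.44e-05, or adjusted p = 0.0661 with an estimated correlation. Fatty acid oxidation gave 0 and 2 of 24 (1 and 8 adjusted over the list alone). Its median was -0.28 (-0.44 without LF-KO-2), with a camera adjusted p of 0.000226, or adjusted p = 0.312 with an estimated correlation. The circadian clock list gave 0 and 4 of 16 (0 and 7 adjusted over the list alone), with Cry1 at -1.04 ± 0.19. Its median was -0.48, with a camera adjusted p of 0.00024, or adjusted p = 0.0988 with an estimated correlation. Bile acid genes gave 0 and 1 of 16 (0 and 3 adjusted over the list alone), with Slc10a1 at -1.11 ± 0.17. Its median was -0.28 (-0.18 without LF-KO-4), with a camera adjusted p of 0.00171, or adjusted p = 0.27 with an estimated correlation. The lipid droplet list was not called, with 1 and 0 of 13 (3 and 2 adjusted over the list alone), Lpl up by 1.60 ± 0.25. Its median was 0.33, with a camera adjusted p of 0.258. Acute phase genes (2 and 0 of 14, camera adjusted p = 0.0824), xenobiotic genes (0 and 2 of 14, 0.0738) and the unfolded protein response (1 and 0 of 14, median -0.08, mean 0.01, 0.991) were not called either. The same held for T and NK cell markers (median 0.46, camera adjusted p = 0.125), B and plasma cell markers (-0.25, 0.617), de novo lipogenesis (-0.12, 0.584), erythroid markers (0.20, 0.324) and sex-biased genes (-0.14, 0.168), each with 0 members called by edgeR. The gene calls named in this group were lost without LF-KO-3 or LF-KO-4.

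Of the 637 genes called in HF-KO vs LF-KO, 632 had every HF-KO library beyond the LF-KO mean, which is no separate support since the same libraries gave the calls. In edgeR, higher and lower genes numbered 0 and 0 without LF-KO-3 and 3 and 1 without LF-KO-4, so every gene call above was lost without LF-KO-3, and of the genes named above Mmp13 alone kept its call without LF-KO-4. Without LF-KO-3 the smallest adjusted p of edgeR's quasi-likelihood test was 0.061, 1943 genes had an unadjusted p under 0.05 where 692 are expected by chance, and DESeq2 called 478 higher and 168 lower genes and limma-voom 0 and 0. Without LF-KO-4, 2004 genes had an unadjusted p under 0.05 in edgeR where 692 are expected. DESeq2 then called 520 higher and 181 lower genes and limma-voom 0 and 1. The edgeR counts were 243 and 83 without LF-KO-1, 221 and 44 without HF-KO-1, 868 and 346 without HF-KO-2, 325 and 60 without HF-KO-4, and 161 and 31 without HF-KO-6, while the lower genes alone moved to 244 without LF-KO-2, 57 without HF-KO-3 and 63 without HF-KO-5. Scaling by library size alone shifted the median of all genes by 0.18 and gave 903 higher and 49 lower genes (94.9% higher, against 77.4%).

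On the LF diet, LF-KO vs LF-C asks what the labelled knockout alters without the HF diet, and no gene passed the test. Among the named list members were Stab1, a scavenger receptor of sinusoidal endothelium, at 44.2 ± 14.1 CPM in LF-KO and 82.4 ± 14.2 in LF-C, Sqle, an enzyme of cholesterol synthesis, at 36.6 ± 11.6 and 15.9 ± 6.37 CPM, and Clec4f, a Kupffer cell receptor, at 114 ± 13.5 and 229 ± 152 CPM. Their log2 fold changes were -0.93 ± 0.27, 1.19 ± 0.34 and -1.05 ± 0.40, each with an adjusted p of 0.704 in edgeR's quasi-likelihood test. Cidec stood at 8.05 ± 3.14 and 10.2 ± 3.79 CPM (log2 -0.37 ± 0.36, adjusted p = 0.722). In edgeR, 0 of 13056 genes were higher and 0 lower, with a smallest adjusted p of 0.5757, and 554 genes had an unadjusted p under 0.05 where 653 are expected by chance. DESeq2 called 2 higher and 3 lower genes, limma-voom 0 and 0, limma on FPKM 1 and 0, and edgeR with all 19 libraries in 1 fit 1 and 0, while without LF-C-2 edgeR called 1 lower gene.

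As groups, 3 of the lists were called in LF-KO vs LF-C, each without a called member. The endothelial list was lower (0 and 0 of 12 called, 0 and 2 adjusted over the list alone). Its median was -0.48, with a camera adjusted p of 7.12e-06, or adjusted p = 0.558 with an estimated correlation. Kupffer cell markers were lower in 4 of 4 LF-KO libraries (0 and 0 of 9, 0 and 0 adjusted over the list alone). Its median was -0.66 (-0.29 without LF-C-2), with a camera adjusted p of 0.0272, or adjusted p = 0.584 with an estimated correlation. Cholesterol synthesis was higher in 4 of 4 (0 and 0 of 24, 0 and 0 adjusted over the list alone). Its median was 0.21 (0.47 without LF-C-1, 0.11 without LF-C-2, 0.14 without LF-C-3), with a camera adjusted p of 0.0303, or adjusted p = 0.884 with an estimated correlation. The Kupffer call was lost without LF-C-3 or LF-KO-3 and the cholesterol call without LF-C-3, LF-C-4 or LF-KO-2, at adjusted p-values up to 0.125 and 0.394. The lipid droplet list had a median of -0.37 and a camera adjusted p of 0.0873. Median, mean and test did not share a sign for acute phase, de novo lipogenesis and unfolded protein response genes, none of them called. Krt19, a keratin of bile ducts, and Acta2, a smooth muscle actin, were at 18.3 ± 34.1 and 17.8 ± 25.4 CPM in LF-C, against 1.25 ± 0.480 and 3.38 ± 0.477 in LF-KO. LF-C-2 was at 69.5 CPM for Krt19 and 55.9 for Acta2, and without it the log2 fold changes were -0.01 and -0.62.

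On the HF diet, HF-KO vs HF-C asks what the labelled knockout alters, and genes of lipid storage and of matrix were lower while genes of hepatocyte function were higher in the KO-labelled livers. Cidec fell from 182 ± 37.1 CPM in HF-C to 12.4 ± 4.68 in HF-KO, a log2 fold change of -3.83 ± 0.25. Plin4, a lipid droplet coat protein (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803, overlapping Hdgfrp2), fell from 118 ± 17.6 to 5.81 ± 1.65 CPM (log2 -4.31 ± 0.20). Vnn1, a pantetheinase induced by PPARα (ENSMUSG00000037440, chromosome 10, 23894688 to 23905343), fell from 146 ± 22.0 to 37.2 ± 9.10 CPM (-1.94 ± 0.17). Slco1a1 (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962) rose from 19.8 ± 7.79 to 210 ± 101 CPM (3.44 ± 0.46). In edgeR's quasi-likelihood test the adjusted p-values were 1.76e-06 for Cidec, 8.46e-08 for Plin4, 2.15e-05 for Vnn1 and 0.000788 for Slco1a1, with 6 of 6 HF-KO libraries beyond the HF-C mean for each. For Cidec, Plin4 and Slco1a1, named as largest changes, the rule for naming fixed that count. Of 13915 genes tested, 605 were higher and 755 lower (9.77%), and 3944 had an unadjusted p under 0.05 where 696 are expected by chance.

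Lipid droplet and fat oxidation genes fell in the KO-labelled livers. The lipid droplet list had 0 higher and 10 lower of 15 (0 and 11 adjusted over the list alone), including Cidea from 34.4 ± 12.1 to 0.137 ± 0.122 CPM (log2 -7.78 ± 0.44; its position overlaps B430212C06Rik) and Aqp7 (-3.14 ± 0.27), with a median of -0.92, a mean of -1.85 and a camera adjusted p of 5.75e-13. That call held with an estimated correlation (adjusted p = 0.0441 with an estimated correlation). Adipocyte markers gave 0 and 2 of 5 (0 and 2 adjusted over the list alone), Cidec and Cfd, the latter an adipokine of the complement system at -5.94 ± 0.55. Its median was -0.49, with a camera adjusted p of 0.00542, or adjusted p = 0.108 with an estimated correlation, and a median of 0.04 when no filter was set on low counts. Fatty acid oxidation and PPARα targets gave 0 and 8 of 24 (0 and 9 adjusted over the list alone), with Acot2 at -1.28 ± 0.18 and Pdk4, which restrains glucose oxidation, at -1.36 ± 0.26. Its median was -0.22, with a camera adjusted p of 1.89e-05, or adjusted p = 0.224 with an estimated correlation. De novo lipogenesis was not called (1 and 0 of 17, median 0.08, camera adjusted p = 0.138).

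Matrix, macrophage, bile duct and cell cycle genes fell as well. In the matrix list 0 rose and 18 of 25 fell (0 and 22 adjusted over the list alone), with Col3a1 from 232 ± 68.3 to 82.7 ± 38.0 CPM (log2 -1.46 ± 0.30) and Col1a2 from 106 ± 28.4 to 33.5 ± 20.1 CPM (-1.64 ± 0.35). Its median was -1.04, with a camera adjusted p of 3.34e-12, or adjusted p = 0.178 with an estimated correlation. Recruited macrophage markers gave 0 and 6 of 14 (0 and 9 adjusted over the list alone), with Gpnmb from 64.1 ± 8.82 to 19.7 ± 8.15 CPM (-1.67 ± 0.25) and Itgax at -1.21 ± 0.24. Its median was -0.62, with a camera adjusted p of 1.9e-06, or adjusted p = 0.169 with an estimated correlation. Cell cycle genes gave 0 and 6 of 16 (0 and 10 adjusted over the list alone), with Mki67 at -0.99 ± 0.18. Its median was -0.68, with a camera adjusted p of 3.16e-07, a call that held with an estimated correlation (adjusted p = 0.0441 with an estimated correlation). Cholangiocyte markers gave 0 and 5 of 10 (0 and 8 adjusted over the list alone), with Krt19 at -1.32 ± 0.27 and Spp1 at -1.35 ± 0.28. Its median was -0.96, with a camera adjusted p of 3.93e-05, or adjusted p = 0.169 with an estimated correlation. Chemokines gave 1 and 2 of 17 (1 and 6 adjusted over the list alone). Its median was -0.52, with a camera adjusted p of 0.00542, or adjusted p = 0.446 with an estimated correlation. Acute phase genes gave 0 and 4 of 14 (0 and 6 adjusted over the list alone). Its median was -0.17, with a camera adjusted p of 0.0234, or adjusted p = 0.446 with an estimated correlation. The acute phase call was lost without HF-C-4, HF-KO-4 or HF-KO-5, at adjusted p-values up to 0.0944, and its median was -0.09 without HF-C-4, -0.30 without HF-KO-2, -0.11 without HF-KO-5 and -0.30 without HF-KO-6.

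Hepatocyte and sterol genes rose in the KO-labelled livers on the HF diet. Cholesterol synthesis and SREBP2 targets gave 13 higher and 0 lower of 24 (14 and 0 adjusted over the list alone), with Idi1 at 1.46 ± 0.30 and Insig1, which holds back sterol synthesis, at 1.04 ± 0.20. Its median was 0.56, with a camera adjusted p of 1.6e-07, or adjusted p = 0.222 with an estimated correlation. The hepatocyte list gave 7 and 0 of 14 (9 and 0 adjusted over the list alone). Its median was 0.43, with a camera adjusted p of 5.07e-06, or adjusted p = 0.169 with an estimated correlation. Methionine metabolism gave 7 and 1 of 20 (9 and 1 adjusted over the list alone), with Bhmt2 at 0.54 ± 0.11. Its median was 0.33, with a camera adjusted p of 0.000717, or adjusted p = 0.108 with an estimated correlation. Bile acid genes gave 5 and 1 of 16 (7 and 1 adjusted over the list alone), with Slc10a1 at 0.75 ± 0.13 and Cyp7b1 at 1.33 ± 0.22. Its median was 0.30, with a camera adjusted p of 0.00283, or adjusted p = 0.258 with an estimated correlation. Xenobiotic genes gave 5 and 1 of 14 (8 and 3 adjusted over the list alone), with Cyp1a2 at 1.33 ± 0.23 and Cyp2c29, of a shared family, at 1.79 ± 0.19. Its median was 0.45, with a camera adjusted p of 0.00542, or adjusted p = 0.446 with an estimated correlation. Sex-biased liver genes gave 1 and 0 of 11 (4 and 0 adjusted over the list alone), the 1 being Cyp2b9, which is higher in females, at 1.51 ± 0.45 (adjusted p = 0.0487). Its call was lost without HF-C-2 (0.112), HF-C-3 (0.106), HF-C-4 (0.0772), HF-C-5 (0.117), HF-KO-1 (0.0781), HF-KO-3 (0.0665), HF-KO-4 (0.0652) or HF-KO-6 (0.0749). The list's median was 0.40, with a camera adjusted p of 0.0167, or adjusted p = 0.147 with an estimated correlation. It holds genes of both biases, so its direction is not a shift toward either sex. Cyp2d9 and Elovl3, higher in males, were at 0.66 and 1.02 without being called. Hsd3b5, which is in none of the lists, rose from 0.245 ± 0.187 to 18.0 ± 15.8 CPM (log2 6.17 ± 0.87). With so low a level in HF-C the size of this rise is uncertain, and the authors' deposited log2 fold change was 1.72. Erythroid markers gave 3 and 0 of 5 (4 and 0 adjusted over the list alone). Its median was 0.94, with a camera adjusted p of 0.00261, or adjusted p = 0.224 with an estimated correlation.

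Other cell types and pathways were not called as lists in HF-KO vs HF-C. Kupffer cell markers gave 1 and 0 of 9 (median 0.24, camera adjusted p = 0.0752), with Cd163 up from 2.11 ± 1.40 to 13.8 ± 8.50 CPM, endothelial markers 0 and 0 of 12 (0.16, 0.148), T and NK cell markers 0 and 1 of 13 (-0.32, 0.0727) and glucose metabolism 1 and 4 of 15 (-0.02, 0.427), with Igfbp1 down by 1.63 ± 0.19 on the log2 scale. Median and mean differed in sign for stellate cell markers (median -0.16, mean 0.05, camera adjusted p = 0.947) and the unfolded protein response (median 0.11, mean -0.01, camera adjusted p = 0.795), and median, mean and test did not share a sign for interferon genes (median 0.02, camera adjusted p = 0.947) and NRF2 targets (median -0.01, camera adjusted p = 0.961). The called lists moved in 6 of 6 HF-KO libraries except chemokines, acute phase and erythroid markers, with 5 of 6. HF-KO-2, whose deviation from its group had a rank correlation of -0.428 with gene length, also had the highest Pparg level in CPM (108, against 94.0 in HF-KO-6). In FPKM the order was the other way, at 52.9 in HF-KO-2 and 54.4 in HF-KO-6.

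Of 1360 genes called in HF-KO vs HF-C, 1347 had every HF-KO library beyond the HF-C mean, again no separate support since the same libraries gave the calls. Higher and lower genes numbered 377 and 469 without HF-C-1, 310 and 456 without HF-C-2, 274 and 430 without HF-C-4, 324 and 404 without HF-C-5 and 305 and 405 without HF-KO-3. Scaling by library size alone shifted the median of all genes by -0.13 and gave 345 higher and 1016 lower genes (25.3% higher, against 44.5%), and it shifted the median of LF-KO vs LF-C by 0.13.

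**Figure D3:**
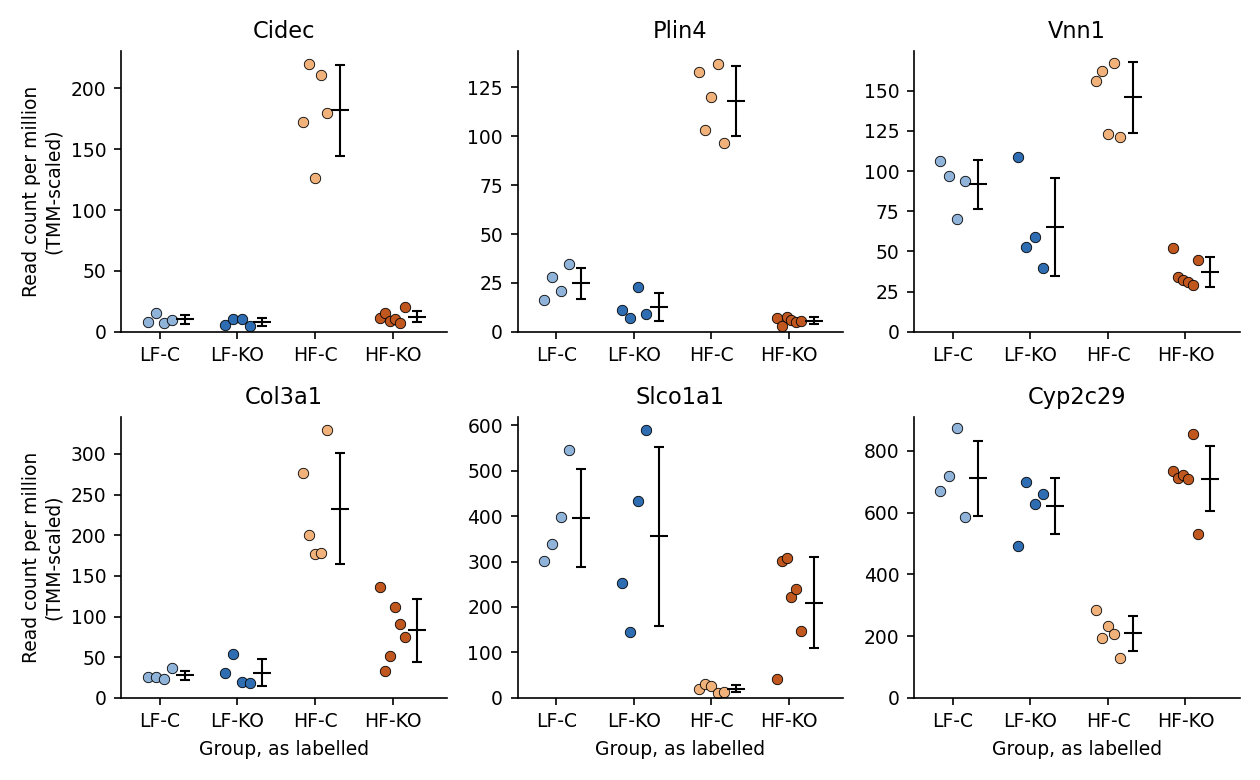
Level of Cidec, Plin4, Vnn1, Col3a1, Slco1a1 and Cyp2c29 in each of the 19 livers, in TMM-scaled CPM (vertical axes), by group (horizontal axes), with a point per library and each group's mean as a dash with its SD as an error bar. Cidec has a mean of 182 CPM in HF-C and of 8.05 to 12.4 CPM in the other 3 groups.

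Whether the labelled knockout acted differently on the 2 diets was tested as the difference of the KO effects, and the lipid droplet genes Cidec and Plin4 had the smallest adjusted p. Cidec was at 10.2, 8.05, 182 and 12.4 CPM in LF-C, LF-KO, HF-C and HF-KO, a difference of -3.49 ± 0.43 on the log2 scale, and Plin4 at 24.8, 12.5, 118 and 5.81 CPM, a difference of -3.31 ± 0.42. Cyp2c29 (ENSMUSG00000003053, chromosome 19, 39269405 to 39330713, a member of a shared family that overlaps Cyp2c53-ps) was at 711, 620, 210 and 710 CPM, a difference of 1.99 ± 0.28. Susd4 (ENSMUSG00000038576, chromosome 1, 182763860 to 182896598), a complement regulator, differed by 2.37 ± 0.39 and Fam83a (ENSMUSG00000051225, chromosome 15, 57985419 to 58011009) by -3.10 ± 0.48. In edgeR's quasi-likelihood test the adjusted p-values were 0.000764 for Cidec, 0.000764 for Plin4, 0.0025 for Cyp2c29, 0.0148 for Susd4 and 0.00784 for Fam83a, and these 5 calls held without any single library. Of 14391 genes tested, 18 differed upward and 11 downward, and 1856 had an unadjusted p under 0.05 where 720 are expected by chance. Pparg differed by 0.28 ± 0.52 (adjusted p = 0.856), or by -0.08 without LF-C-1.

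By list, the difference was downward for lipid droplet genes (0 and 2 of 15 called, 0 and 6 adjusted over the list alone; median -0.81, camera adjusted p = 1.21e-07, or adjusted p = 0.0869 with an estimated correlation). It was downward for matrix genes too (0 and 0 of 25, 0 and 10 adjusted over the list alone; median -1.04, camera adjusted p = 4.27e-10, or adjusted p = 0.181 with an estimated correlation), where Col3a1 differed by -1.62 ± 0.49 without passing the test (adjusted p = 0.18). Fatty acid oxidation genes gave 0 and 0 of 24 (0 and 4 adjusted over the list alone). Its median was -0.38, with a camera adjusted p of 0.000163, or adjusted p = 0.344 with an estimated correlation. Cell cycle genes gave 0 and 0 of 16 (0 and 1 adjusted over the list alone). Its median was -0.41, with a camera adjusted p of 0.00494, or adjusted p = 0.349 with an estimated correlation. The difference was upward for endothelial markers (0 and 0 of 12, 2 and 0 adjusted over the list alone). Its median was 0.71, with a camera adjusted p of 3.69e-06, or adjusted p = 0.181 with an estimated correlation. Kupffer cell markers gave 1 and 0 of 9 (3 and 0 adjusted over the list alone). Its median was 0.81, with a camera adjusted p of 0.000174, or adjusted p = 0.181 with an estimated correlation. Erythroid markers gave 1 and 0 of 5 (5 and 0 adjusted over the list alone). Its median was 1.95, with a camera adjusted p of 0.000106, or adjusted p = 0.181 with an estimated correlation. Without LF-C-2, the Kupffer, erythroid and cell cycle medians were 0.35, 1.05 and -0.70, and the cell cycle median was also -0.67 without LF-C-1 and -0.23 without LF-C-4. The cell cycle call was lost without LF-C-3 or LF-C-4, at adjusted p-values up to 0.136.

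Lists of hepatocyte metabolism differed upward. Hepatocyte markers gave 0 and 0 of 14 (3 and 0 adjusted over the list alone). Its median was 0.50, with a camera adjusted p of 0.000184, or adjusted p = 0.089 with an estimated correlation. Methionine genes gave 0 and 0 of 20 (3 and 0 adjusted over the list alone). Its median was 0.40, with a camera adjusted p of 0.000612, or adjusted p = 0.0869 with an estimated correlation. Bile acid genes gave 1 and 0 of 16 (4 and 0 adjusted over the list alone), the 1 being Slco1a1 at 3.58 ± 0.63. Its median was 0.29, with a camera adjusted p of 0.00376, or adjusted p = 0.344 with an estimated correlation. The Slco1a1 call was lost without LF-KO-1 (adjusted p = 0.0519) or LF-KO-2 (0.0537). Xenobiotic genes gave 3 and 0 of 15 (5 and 1 adjusted over the list alone). Its median was 0.04, with a camera adjusted p of 0.039, or adjusted p = 0.462 with an estimated correlation. The bile acid median was 0.52 without LF-KO-4 and 0.19 without HF-C-5, and its call was lost without LF-C-4 (0.0718). The xenobiotic median was -0.21 when scaled by library size alone, -0.10 without LF-C-4, -0.18 without LF-KO-2 and -0.08 without HF-C-5, and its call was lost without LF-C-1, LF-C-4, LF-KO-1, LF-KO-2, HF-C-5, HF-KO-1 or HF-KO-2, at adjusted p-values up to 0.289. Median, mean and test did not share a sign for adipocyte, glucose, sex-biased and T and NK cell genes, none of them called.

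Higher and lower counts of this difference were 2 and 5 without LF-KO-1, 3 and 4 without LF-KO-2, 11 and 7 without HF-C-1 and 29 and 19 without HF-KO-1, and the higher count alone was 11 without LF-KO-3, HF-KO-3 or HF-KO-5. The lower count alone was 19 without LF-C-3, 17 without LF-KO-4, 5 without HF-C-2, 7 without HF-C-4 and 7 without HF-KO-4. Library size alone shifted the median of all genes by -0.23 and gave 8 higher and 7 lower genes.

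Set side by side, the diet effects of both genotypes ran in the same direction for most genes. Across 13431 genes, which are not independent replicates, the log2 fold changes of HF-KO vs LF-KO and HF-C vs LF-C, which share no libraries, had a Pearson r of 0.681, and 69.2% had the same sign. Both diet contrasts called 330 genes higher (50.1 expected by chance) and 94 lower (10.4 expected), and 1 in opposite directions. Of the genes that the diet raised in control mice, 449 (30.7%) were lower in HF-KO than in HF-C, where 80.5 are expected by chance, and of those it lowered 239 (24.6%) were higher, where 41.9 are expected. These contrasts share the HF-C libraries, which alone gives a negative correlation: r was -0.635 across 13708 genes, against -0.483 on average in 5 simulations without change. The covariance was -0.267, against -0.0424 in those simulations. With the HF-C libraries split so that no library served both contrasts, r had a median of -0.553 over 10 splits (-0.625 to -0.461), and 28.5 genes (19 to 44) and 10.5 genes (5 to 18) were called in these opposite directions. The LF-KO vs LF-C and HF-KO vs HF-C contrasts, without shared libraries, had an r of 0.173.

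At an adjusted p under 0.05 in the authors' own deposited results, 1881 genes were higher and 1994 lower in HF-C vs LF-C, 887 and 448 in HF-KO vs LF-KO, 2 and 3 in LF-KO vs LF-C, and 1055 and 1218 in HF-KO vs HF-C. Of the genes that edgeR called, 2444 of 2457, 636 of 637 and 1360 of 1360 were in those results with the same direction, for HF-C vs LF-C, HF-KO vs LF-KO and HF-KO vs HF-C. The 1 edgeR call of HF-KO vs LF-KO that the authors' results did not make was Gpnmb, with a deposited log2 fold change of 0.91. Both sets of calls come from the same counts, so their overlap is no independent support.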

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

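The tests chosen only after the result was seen were the 3 on the Pparg level, the comparison of macrophage and matrix markers with endothelial markers, the fits without LF-C-1 and LF-C-2 or without HF-KO-2 and HF-KO-6, the length offset, the quality weights and the fits of other tools without LF-KO-3 or LF-KO-4.

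Pparg counts were higher in the libraries labelled HF-KO than in HF-C, although the labels describe a knockout in hepatocytes. An exchange of the HF-KO and HF-C labels is argued against by the lipid droplet list, textbook targets of PPARγ among them, whose mean log2 fold change was -1.85 (median -0.918, SE over its 15 members 0.548). That SE is a spread over genes, not over mice. By library, the list mean of all 6 HF-KO libraries lay below that of every HF-C library. The argument takes as given that PPARγ raises these genes. Adipocytes in the samples are argued against as well: the largest rise in mean CPM among Adipoq, Plin1, Cfd and Fabp4 from HF-C to HF-KO was 0.0231, and Cfd and Fabp4 changed by -6.24 and -10.5 CPM, while Pparg rose by 43.3 CPM (SE 10.6). Reads from exons left in place in the deleted gene may give this pattern, but the log2 fold change of 1.47 comes from a count per gene, which does not separate exons, so this cannot be told apart from other sources of Pparg reads without the reads themselves.

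More genes were called for diet in the control genotype than in the KO-labelled genotype, 2457 against 637, a ratio of 3.86. Without LF-C-1 and LF-C-2, 4213 genes were called. That fit keeps LF-C-3 and LF-C-4 alone, with like correlations with gene length (0.435 and 0.428). More calls were likely once a library that stands apart was left out, so this count decides little. Without LF-C-1 alone 1691 genes were called and without LF-C-2 alone 3478, both more than 637. The spread from HF-KO-2 and HF-KO-6 is argued against, since HF-KO vs LF-KO called 1062 genes without them, still fewer than in the control genotype. A gene length trend between libraries is argued against by a ratio of 3.75 with the length offset (3233 against 863). The ratio itself depended on the test, at 1.58 with quality weights (3022 against 1917), and edgeR called 0 genes in HF-KO vs LF-KO without LF-KO-3, where DESeq2 called 478 higher and 168 lower. The difference of the KO effects between diets is, by its terms, also the diet effect in KO-labelled mice minus that in control mice. In edgeR it was called for 29 of 14391 genes, Cidec among them. The matrix list had a median of -1.04 in it (camera adjusted p = 4.27e-10, or 0.181 with an estimated correlation). For the genes not called there, a weaker diet response in KO-labelled livers stays open as a hypothesis.

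The matrix and macrophage lists were lower in HF-KO than in HF-C. A higher share of hepatocytes alone would lower every other cell type alike, but the macrophage list mean moved by -0.935 relative to the sinusoidal endothelial list mean (log2 CPM, exact permutation p = 0.0195) and the matrix list mean by -1.29 (exact permutation p = 0.00433). The endothelial list is not a fixed reference. Camera at the preset correlation called it lower in HF-C vs LF-C (median -0.41) and in LF-KO vs LF-C (median -0.48). A change of the endothelial genes themselves may thus add to these values. HF-KO-2 is argued against, since without it the matrix median was -0.863 (camera adjusted p = 8.68e-13) and the macrophage median -0.68. With all libraries and an estimated correlation, however, neither list stayed called (adjusted p = 0.178 for matrix and 0.169 for macrophages). The length offset left them at -0.996 and -0.63, which argues against a gene length trend as the whole source. Less recruitment of macrophages and less scar tissue in the KO-labelled livers may be the reason, a hypothesis that these counts from whole liver did not test further.

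Whether other splits of the same libraries call as many genes was counted for each comparison. Chance is unlikely for HF-C vs LF-C (1 of 100 splits as large, the real split, with 2457 genes against at most 2 in the others). It is also unlikely for HF-KO vs LF-KO (1 of 100, 637 against at most 92) and for HF-KO vs HF-C (1 of 100, 1360 against at most 0). For the difference of the KO effect between diets the count was 1 of 100, with 29 genes against at most 2. Those splits exchanged KO and C labels within each diet, which removes the KO effect on the HF diet as well. They therefore cannot decide whether a difference between the diets arose by chance. With 100 splits counted, 1 of 100 is the smallest share possible, so chance is not excluded. The count decides nothing for LF-KO vs LF-C, where the real split called 0 genes, so that 35 of 35 splits called as many by construction.

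Single libraries lay far from the rest of their group in 16 of 196 groups tested (49 measures in each of the 4 groups), where independent, normally spread measures would give about 1 in 20 groups, or 9.8. Most measures were levels of related genes, some near 0, so these counts do not decide whether there is an excess. LF-C-2 did so in 7 and LF-KO-2 in 4 of them. The spread of gene levels around the median of the other libraries of the group was 1.27 log2 units in LF-C-2 (0.581 to 0.672 in the others), 0.872 in HF-KO-2 (0.309 to 0.427) and, as the lowest of its group, 0.331 in LF-KO-4 (0.387 to 0.398). LF-C-2 had the highest level in its group of Sprr1a (0.525 CPM), Cidea (1.5), Ly6d (9.75), Mup11 (307), Gpnmb (11.3) and Ubd (5.93). LF-KO-2 had the highest level in its group of Sprr1a (4.74 CPM), Cx3cr1 (3.76), Trem2 (6.22) and Ccl2 (2.46). HF-C-3 had the highest Hsd3b5 (0.574 CPM) and Trem2 (26.0) of its group, and HF-KO-6 the highest Fam83a (12.5).

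The KO effect differed between diets in edgeR's test of the difference for each of the 10 genes with the smallest adjusted p. The differences on the log2 scale were -3.49 for Cidec, -3.31 for Plin4, 1.99 for Cyp2c29, -3.10 for Fam83a, 2.37 for Susd4, 2.13 for Cyp2c37, 2.15 for BC089597, 2.78 for Lrtm1, 3.58 for Slco1a1 and 2.49 for Cyp2c54. The last 5 lost their calls without LF-KO-1 (adjusted p 0.0514 to 0.0519) or LF-KO-2 (0.0531 to 0.0573). Camera called the difference for lists with medians of 0.285 (bile acid), -0.407 (cell cycle), 1.95 (erythroid), -1.04 (matrix), -0.383 (fatty acid oxidation), 0.497 (hepatocyte), 0.807 (Kupffer), -0.809 (lipid droplet), 0.705 (endothelial), 0.404 (methionine) and 0.0429 (xenobiotic), and 0 of these calls held with an estimated correlation.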

How the results depend on the processing

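The tests chosen only after the result was seen were the fits without LF-C-1 and LF-C-2, without HF-KO-2 and HF-KO-6 or without LF-C-2 and HF-KO-2, the length offset and the quality weights. Counts are given as genes higher and lower in edgeR unless another tool is named. Median-of-ratios scaling and a filter at a mean of 1 CPM kept all 15 counts within 1.5 times and all 63 called lists. With library size alone the counts were 2729 and 327 (HF-C vs LF-C), 903 and 49 (HF-KO vs LF-KO), 345 higher (HF-KO vs HF-C) and 8 and 7 (the difference of the KO effect), 5 lists were called in LF-KO vs LF-C, and Pparg in HF-KO vs LF-KO passed at 1.57 (adjusted p = 0.0327). With no filter Pparg in that comparison was 1.44 (adjusted p = 0.0365), 5 lists were called in LF-KO vs LF-C and 17 genes were lower in the difference. The cause of these changes, and of those below, was not tested, except where a stricter threshold or fewer libraries change a count by construction.

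DESeq2 gave 2018 lower (HF-C vs LF-C), 883 and 447 (HF-KO vs LF-KO), 2 and 3 (LF-KO vs LF-C), 1055 and 1217 (HF-KO vs HF-C) and 105 and 91 (the difference), with Pparg in HF-KO vs LF-KO at 1.44 (adjusted p = 0.00448). Limma-voom gave Pparg 1.58 there (adjusted p = 0.0408) and 10 and 6 genes in the difference. Limma on FPKM gave 3440 and 341 (HF-C vs LF-C), 872 and 42 (HF-KO vs LF-KO), 1 higher (LF-KO vs LF-C), 354 and 1169 (HF-KO vs HF-C), and 103 lower in the difference, with that Pparg at 1.67 (adjusted p = 0.0174). An adjusted p under 0.01 left 736 and 301 (HF-C vs LF-C), 0 and 0 (HF-KO vs LF-KO), 142 and 179 (HF-KO vs HF-C), and 1 and 3 (the difference). An absolute log2 fold change of at least 1 left 534 lower, 37 lower, and 148 and 311 in HF-C vs LF-C, HF-KO vs LF-KO and HF-KO vs HF-C. All 19 libraries in 1 fit gave 1883 lower (HF-C vs LF-C), 94 lower (HF-KO vs LF-KO), 1 higher in LF-KO vs LF-C with 1 list called, and 197 and 334 (HF-KO vs HF-C), with that Pparg at 1.44 (adjusted p = 0.0335). In none of the comparisons did every pair of same-number libraries correlate over 0.1, so the mice were taken to share only a number. After removal of group means, same-number libraries correlated at -0.183 to 0.0607 in HF-C vs LF-C, 0.0655 to 0.18 in HF-KO vs LF-KO, -0.148 to 0.182 in LF-KO vs LF-C and -0.0944 to 0.0931 in HF-KO vs HF-C. With the replicate block the counts were 545 and 155 (HF-C vs LF-C), 154 and 24 (HF-KO vs LF-KO), 306 and 480 (HF-KO vs HF-C), and 5 lower in the difference, 5 lists were called in LF-KO vs LF-C, and that Pparg was 1.54 (adjusted p = 0.0308). With an estimated correlation 1, 1, 0, 2 and 0 lists stayed called in HF-C vs LF-C, HF-KO vs LF-KO, LF-KO vs LF-C, HF-KO vs HF-C and the difference. With shared libraries split, the correlation of HF-KO vs HF-C with HF-C vs LF-C was -0.553 and that of LF-KO vs LF-C with HF-C vs LF-C had a median of 0.206 over 3 splits that ranged from -0.175 to 0.292, so its sign is open. Unsplit it was 0.448, against 0.537 in simulations without change, with a covariance of 0.153 against 0.0539.

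Among the alternatives chosen after seeing the data, fits without LF-C-1 and LF-C-2 gave 2331 and 1882 (HF-C vs LF-C), 2 lower and 10 lists (LF-KO vs LF-C), and 44 and 21 with 18 lists (the difference). Without HF-KO-2 and HF-KO-6 there were 754 and 308 (HF-KO vs LF-KO), 1053 and 1267 (HF-KO vs HF-C) and 17 lists in the difference. Without LF-C-2 and HF-KO-2 the difference had 39 and 24 genes and 19 lists. The length offset gave 1633 lower (HF-C vs LF-C), 241 lower (HF-KO vs LF-KO) and 40 and 20 (the difference), with that Pparg at 1.42 (adjusted p = 0.0397). Quality weights gave 1222 and 695 (HF-KO vs LF-KO), 1259 and 1408 (HF-KO vs HF-C) and 59 and 44 (the difference), with that Pparg at 1.48 (adjusted p = 0.00846).

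Reversed signs were seen for Clec4f in HF-C vs LF-C, not called at -0.62, with limma on FPKM (0.0109), without LF-C-1 and LF-C-2 (0.12) and with quality weights (0.0081), for Krt19 in LF-KO vs LF-C without LF-C-1 and LF-C-2 (0.0757), and for Pparg in the difference without LF-C-1 (-0.0827) and without HF-KO-2 and HF-KO-6 (-0.108), none of them called. Leaving out each library in turn gave 1001 to 2051 higher, 450 to 1629 lower and 15 to 21 lists in HF-C vs LF-C. It gave 0 to 868, 0 to 346 and 17 to 20 in HF-KO vs LF-KO, 0 to 0, 0 to 1 and 1 to 8 in LF-KO vs LF-C, 274 to 819, 404 to 995 and 15 to 18 in HF-KO vs HF-C, and 2 to 29, 4 to 19 and 8 to 19 in the difference. Pparg ranged from 0.96 to 1.51 in HF-C vs LF-C, 1.21 to 1.79 in HF-KO vs LF-KO, 0.81 to 1.51 in LF-KO vs LF-C, 1.29 to 1.56 in HF-KO vs HF-C, past the threshold each time, and -0.0827 to 0.618 in the difference. Of the called lists, 699 values kept their call over left-out libraries and 24 lost it. Of the named genes, 2621 values kept their side of the threshold, 525 lost a call, 23 gained one and 1 reversed. At the sizes of LF-KO vs LF-C, simulated changes of 2-fold were recovered in 7% of genes and of 4-fold in 84%, and smaller changes were not simulated, so 0 calls on the LF diet do not exclude changes of 2-fold. Changes in genes with a mean under 5 CPM were not simulated either.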

Other observations

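All tests named here were chosen before the result was seen, and levels are given as values. Genes of the Y chromosome were seen in each of the 19 livers: Ddx3y ranged from 30.6 CPM in LF-C-1 to 102 in HF-KO-2, Eif2s3y from 39.1 to 81.7, Uty from 3.45 to 31.2 and Kdm5d from 3.83 to 26.4, while Xist, the RNA of the silenced X chromosome, ranged from 0 to 0.616. Cyp2d9, a liver enzyme higher in male mice, stood at 1600 ± 305 CPM in LF-C and 470 ± 63.3 in HF-C (log2 fold change -1.80 ± 0.19, edgeR adjusted p = 0.000321, in 5 of 5 libraries). Elovl3, a fatty acid elongase that is also higher in male mice, stood at 225 ± 171 and 45.0 ± 17.8 CPM (log2 -2.35 ± 0.46, edgeR adjusted p = 0.00657, in 5 of 5 libraries). In HF-KO vs HF-C neither passed edgeR's test, with log2 fold changes of 0.66 for Cyp2d9 (adjusted p = 0.0522) and 1.02 for Elovl3 (adjusted p = 0.0677). In HF-C vs LF-C, Cyp2d9 and Elovl3 were the only called members of the sex-biased list. Of its 11 tested members, 6 had a positive and 5 a negative log2 fold change there. The list, which holds genes of both biases, was not called (median 0.04, camera adjusted p = 0.511).

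Ciart, a repressor in the clock, was lower on the HF diet in KO-labelled livers. It stood at 14.9 ± 8.29 CPM in LF-KO and 2.96 ± 1.10 in HF-KO (log2 -2.34 ± 0.42, edgeR adjusted p = 0.0171, in 6 of 6 libraries; its position overlaps C920021L13Rik), and in control mice at 11.1 ± 11.1 in LF-C and 3.14 ± 1.84 in HF-C (log2 -1.83 ± 0.68, adjusted p = 0.0841). The Ciart call was lost without LF-KO-3 or LF-KO-4. The hour of tissue collection is not given in the sources used here.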
